A study of Mus musculus and Danio rerio with 27 samples.

How the data were processed

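RNA-seq libraries were made from mouse dendritic cells sampled every 15 min from 0 to 180 min after LPS, as total RNA and as RNA labelled with 4-thiouridine (4sU) in the last 10 min. Ribosomal RNA was removed before an aliquot was kept as total RNA and the remainder was purified for 4sU, and libraries were strand-specific, per the labels' protocols. Reads were processed with TopHat and Cufflinks on the mm9 mouse genome, and with TopHat on Zv9 for the zebrafish library, per the submitters' processing notes, which give no versions. The deposited tables hold raw read counts per feature of 11444 transcripts, per the file headers and the authors' description: exons, exon-exon junctions, introns, exon-intron boundaries and a further class of features that is both exon and intron. The authors' level tables hold an estimated signal of mature and precursor RNA for 7872 genes in arbitrary units, made from the counts with a binomial model, per the authors' description. The rate tables hold half-lives of the authors' kinetic model, fitted to all times together, per the authors' description, although their headers say rate. The deposited zebrafish table holds levels on a log2 scale, where the base is inferred from its floor and is not written in the file.

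Exonic counts were the sum of exon and exon-exon junction reads and precursor counts the sum of intron and boundary reads, per gene. Reads of the mixed class, at most 2.58% of a total RNA and 2.16% of a 4sU library, were not used in any comparison. For 11 second transcripts the one with the higher mean count was kept, leaving 11433 genes on 20 chromosomes. Symbols came from the reference table of RefSeq genes for 10619 genes, from it with the version suffix removed for 530, from GENCODE names for 48, and 247 genes had none. Positions are those of the deposited tables on mm9. Jun, Junb, Ier2, Il12b and Ifnb1 were not analysed here. Whether the authors' counting used strand or divided reads between similar genes is not stated.

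Each time course was tested with edgeR's quasi-likelihood F-test on the counts, with TMM scaling, filterByExpr and a natural cubic spline of time with 4 degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fitted log2 range of at least 1 over the sampled times, and its direction is the sign of the largest fitted departure from 0 min. Residual degrees of freedom were 8 for total RNA and 7 for 4sU RNA, which lacks 45 min in the count table, so that the planned 13 libraries became 12 and the paired tests used 12 pairs or 24 libraries. The difference of courses was tested as the 4 fraction-by-spline terms with time point as a block, because both libraries of a time point come from 1 RNA sample per the labels' protocols, at adjusted p under 0.05. The 4sU to total ratio was tested as the fraction term with the same block, at adjusted p under 0.05 and at least 2-fold. With 1 series and no replicates, all p-values measure only the scatter of single libraries about smooth curves, and do not cover differences between cultures, animals or labelling runs.

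Fitted changes exceed observed ones in genes that rise steeply from few counts, so observed CPM stand beside many of them. Over called genes the median of fitted minus observed log2 change was 0.03 in total RNA, 0.08 in 4sU RNA and 0.07 in precursors, with the same sign in 99.97%, 99.98% and 100% of genes. A gene with 0 counts at 0 min is given as a bound against 3 counts in that library, and one with 1 to 3 counts as a ratio with an exact 95% interval. Intervals and bounds cover counting error only.

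Gene lists were tested with camera on voom values for 60 min and 180 min against 0 min, with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjustment over lists with at least 5 measured genes, a repeat with an estimated correlation, and fry. The lists were immediate early genes, cytokines and chemokines, NF-kappaB feedback, interferon response, mRNA decay factors, splicing factors, dendritic cell maturation, MHC class II, Toll-like receptor signalling, ribosomal proteins, oxidative phosphorylation, glycolysis, cell cycle, noncoding RNAs, cholesterol synthesis, surface receptors and regulators, replication histones, and markers of dendritic cells, macrophages, neutrophils, B cells, T cells, natural killer cells, plasmacytoid dendritic cells, erythroid cells, mast cells and stromal cells. For cholesterol synthesis only values of single genes are given. Zebrafish lists of maternal and zygotic genes were not matched to any locus. For the 4sU to total ratio and for half-lives, a list's median is given with its percentile among 10000 random lists of the same size matched on mean expression. For the order of rises the time of the fitted maximum and of 50% of the fitted rise within 180 min were taken over genes rising in precursor, exonic 4sU and total RNA.

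Named genes were taken by rule. In each time course they are, among genes past adjusted p 0.05 with a mean log2 CPM of at least 3 and 1 symbol, the 10 with the largest fitted rise and the 10 with the largest fitted fall. For precursors they are the 8 largest rises and 4 largest falls, for the difference of courses the 6 largest each way between 180 and 0 min, for 4sU against total the 8 largest folds each way, and from each list of at least 5 measured genes the 4 with the largest fitted change. Genes behind counts of 5 or fewer were added after their values were seen. The tests, the lists, this rule and the alternatives on scaling by size factors, count filters, DESeq2, spline flexibility, trend shape, thresholds, the time point block, the authors' levels with limma, fry, raw maxima and the other rate tables were chosen before the data were examined. List tests on precursors, library size as the only scaling, junction or intron reads alone, a threshold on the difference of courses and all fits without the 0 and 90 min 4sU libraries were chosen after seeing the data.

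Tests were tried on simulated counts with the real means and library sizes and 200 changed genes. For total RNA 41.8% of genes changed by 1 on the log2 scale, 88.1% by 1.5 and 90.9% by 2 were recovered among 11048, and 3.29% of calls were false. For 4sU RNA these were 25.4%, 58.2% and 81.8% of 11040 genes with 6.78% false, for precursors 8.96%, 67.2% and 83.3% of 11190 with 5.36% false, and for the difference of courses 25.4%, 62.7% and 87.9% of 10661 with 4.10% false. For the 4sU to total ratio 92.5%, 100% and 100% were recovered at 1.25, 1.75 and 2.25, with 0% false. A simulated list of 25 genes changed by 0.5 was called in 10 of 10 draws, and 2 of 200 unchanged lists were called. Genes were simulated independently of each other, so this does not show how often correlated genes give false list calls. Each simulated comparison of genes held 200 changed genes, while 3620 were called in the real total RNA and 8505 in precursors. The recovered and false shares therefore do not cover errors of scaling when many genes change. Nor do they cover errors from 4sU libraries that differ from the others in makeup. Total RNA libraries held 19 to 34.8 M counted reads and 4sU libraries 38.2 to 114.4 M, and genes with few reads at 0 min have wide intervals. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.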

Results

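RNA was followed in dendritic cells of C57BL/6 mice, antigen-presenting cells of the innate immune system, at 13 times from 0 to 180 min, 15 min apart, after lipopolysaccharide (LPS), an outer membrane component of Gram-negative bacteria. The cells took up 4-thiouridine (4sU), a uridine analogue that marks newly made RNA, for the last 10 min before each collection, and each RNA sample was divided into total RNA and purified 4sU RNA. The series asks how production, processing and degradation of RNA are each set over the response. Count tables held 13 total RNA libraries and 12 4sU libraries, with no 4sU column at 45 min, and 1 more library held polyadenylated RNA of zebrafish embryos at the oblong stage. Each time had 1 library per fraction, so no value has a replicate, and every error is the scatter of single libraries about a smooth curve in time. Total RNA libraries held 19 to 34.8 M counted reads (median 27.1 M) and 4sU libraries 38.2 to 114.4 M (median 47.4 M). Exonic reads (exons and exon-exon junctions) came to 10 to 19.7 M in total RNA and 6.02 to 22.0 M in 4sU RNA, and precursor reads (introns and exon-intron boundaries) of the 4sU libraries to 21.5 to 94.4 M.

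Intron reads made up 36.1% to 49.7% of the reads of the total RNA libraries, and spliced reads 91.2% to 93.6% of their junction reads. The 4sU libraries at 0 and 90 min stood apart from the other 10. Spliced reads were 91.5% and 87.4% of their junction reads, against 55.1% to 72.5% in the others, and intron reads 45% and 56.4% of their reads, against 68.4% to 79.3%.

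**Figure D1:**
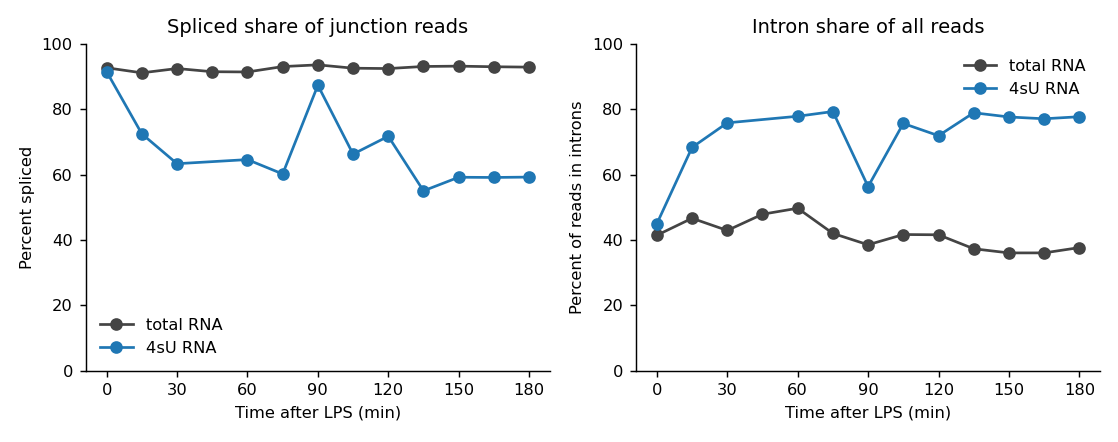
Spliced reads as percent of junction reads (left) and intron reads as percent of all reads (right) of each total and 4sU RNA library, against minutes after LPS. The 4sU library of 45 min is not used here.

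The largest rises in total RNA included those of Ereg, Nos2, Cxcl10, Il6 and Rsad2. Changes below are fitted log2 changes from 0 min at the sampled time of the largest departure, ± SE, and CPM are observed counts, scaled to library size and composition, at 0 min and at that time. With few reads at 0 min, as in Ereg and Areg, the fitted change exceeded the observed one, and the SE does not cover that gap. Ereg, which encodes an epidermal growth factor receptor ligand, rose by 12.67 ± 0.49 to its fitted peak at 105 min, observed from 0.178 to 72.8 CPM, and Areg, another such ligand, by 9.62 ± 0.67 (from 0.178 to 86.1 CPM). Il6, an inflammatory cytokine gene (NM_031168, mm9 chromosome 5, 30339702 to 30346369), rose by 9.90 ± 0.26 (from 1.51 to 1058 CPM). Rsad2, an antiviral gene (NM_021384, mm9 chromosome 12, 27127669 to 27141274), rose by 9.87 ± 0.34 and reached the highest level of this group (from 15.1 to 13342 CPM). Nos2, the inducible nitric oxide synthase, rose by 11.42 ± 0.74 (from 0.267 to 343 CPM), Cxcl10, a chemokine, by 10.59 ± 0.47 (from 2.72 to 1804 CPM), Oasl1 by 10.58 ± 0.65 and Ifit1 by 9.82 ± 0.55, both interferon-induced. Il23a, a cytokine subunit, rose by 10.10 ± 0.43 to 90 min, and the serine protease gene Htra4 by 11.26 ± 0.66. Whether counting used strand or split shared reads is not stated, so values of overlapping or antisense genes such as Htra4 and of members of gene families are uncertain. Adjusted p of these 10 genes lay between 4.63e-15 (Rsad2) and 1.99e-09 (Areg) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

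The largest falls in total RNA included those of Fam214a, Adra2a, Cnr2, Tiam2 and Klf4. C130050O18Rik changed by -5.09 ± 0.43 (from 12.9 to 0.310 CPM), Fam214a by -4.52 ± 0.30 and Adra2a, an adrenergic receptor gene, by -4.39 ± 0.22. Cnr2, a cannabinoid receptor, changed by -4.29 ± 0.22 (from 66.1 to 3.34 CPM), Tmem86a by -4.27 ± 0.29 and the Rac exchange factor gene Tiam2 by -4.20 ± 0.43. Klf4, a transcription factor gene (NM_010637, mm9 chromosome 4, 55540210 to 55544947), changed by -4.12 ± 0.21 (from 40.7 to 2.75 CPM), and Arhgap39 by -3.94 ± 0.40. Dna2, a nuclease and helicase of DNA replication, changed by -3.88 ± 0.20 (from 132 to 8.98 CPM), and Synpo by -3.82 ± 0.28. Adjusted p of these 10 falling genes lay between 1.21e-13 (Cnr2) and 7.56e-09 (Tiam2) by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

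Immune groups rose early or late in total RNA. All 26 measured cytokine and chemokine genes rose (26 adjusted over the list alone), with a median change of 4.28 at 60 min and 4.42 at 180 min (3.17 and 4.36 with the 2 genes at 0 counts at 0 min set to their bound). Csf3 and Il12a had 0 counts at 0 min and were at least 23.2-fold and at least 83.0-fold higher at 180 min, against a floor of 3 counts. Of the 21 immediate early genes, which respond without new protein synthesis, 17 rose and 4 fell (21 adjusted over the list alone), with a median of 2.35 at 60 min. Csrnp1 rose by 5.64 ± 0.29, Dusp2 by 6.34 ± 0.53, Nr4a1 by 5.11 ± 0.36 and Dusp4 by 4.93 ± 0.30, all with their peak at 75 or 90 min. Klf4, Egr2 (-3.17 ± 0.33), Myc (-3.10 ± 0.37) and Klf2 (-1.67 ± 0.29) fell. By 180 min the immediate early median was 0.32, or -0.29 when scaled by library size alone. All 31 interferon response genes rose (31 adjusted over the list alone), with a median of 0.70 at 60 min and 5.4 at 180 min, both the same with the 2 genes at 0 counts set to their bound, or 0.46 and 4.79 with library size alone. Cxcl9, at 0 counts at 0 min, was at least 145-fold higher at 180 min. Of 20 genes of NF-kappaB and its feedback inhibitors 18 rose (18 adjusted over the list alone; medians 1.37 and 2.25), among them Nfkbiz by 7.51 ± 0.41, Tnfaip3 by 4.82 ± 0.31, Cflar by 4.35 ± 0.27 and Nfkbid by 3.32 ± 0.27. Of 20 dendritic cell maturation genes 18 rose (18 adjusted over the list alone; medians 1.19 and 2.48). Cd40 stood at 7.96 ± 0.48, Socs3, a feedback inhibitor of cytokine signalling, at 5.09 ± 0.18, Tnfsf4 at 4.86 ± 0.26 and Cd80 at 3.69 ± 0.18.

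Against all other genes, camera with Benjamini-Hochberg adjustment gave adjusted p = 3.08e-29 at 60 min and 4.14e-18 at 180 min for cytokines and 4.59e-20 and 0.166 for immediate early genes. By the same camera test with Benjamini-Hochberg adjustment, adjusted p = 3.97e-07 and 1.77e-23 for interferon response, 4.48e-19 and 6.04e-12 for NF-kappaB feedback, and 3.09e-17 and 6.57e-11 for maturation. With an estimated correlation the calls at 60 min held for cytokines (adjusted p = 0.0152 with an estimated correlation), immediate early genes (0.0274) and maturation (0.0274), while that of NF-kappaB feedback did not (0.0758) and that of the interferon response did not (0.308). At 180 min none of these held, with adjusted p = 0.105 for cytokines, 0.239 for NF-kappaB feedback, 0.114 for interferon response and 0.114 for maturation with an estimated correlation.

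Regulators of mRNA decay moved both ways. Of 34 such genes 6 rose and 4 fell in total RNA (10 adjusted over the list alone). Zfp36, which directs decay of AU-rich transcripts, rose by 3.77 ± 0.18 to a peak at 60 min (from 41.0 to 522 CPM). Zc3h12c rose by 3.76 ± 0.22 and the endonuclease gene Zc3h12a by 2.83 ± 0.13. Zfp36l1, a paralogue of Zfp36, fell by 2.37 on the log2 scale (SE 0.33), though limma on the authors' own levels gave 2.13 or 2.33 with either pseudocount. Zfp36l2 (-1.85 ± 0.16), Pan2 (-1.20 ± 0.20) and Edc3 (-1.18 ± 0.19) fell. In the Toll-like receptor pathway, which senses LPS, 13 of 27 genes rose and 3 fell (16 adjusted over the list alone). Cd14, a co-receptor of LPS, rose by 2.90 ± 0.21, Tlr7 by 2.61 ± 0.20, Tlr2 by 2.24 ± 0.13 and Tlr3 by 2.2 ± 0.31. Tlr4, the LPS receptor (-1.10 ± 0.18), Tirap (-1.68 ± 0.19) and Ticam2 (-1.25 ± 0.14) fell. The pathway's median was 0.29 at 60 min and 0.52 at 180 min, or 0.04 and -0.09 with library size alone (camera, Benjamini-Hochberg adjusted p = 0.00420 and 0.00822; adjusted p = 0.241 and 0.251 with an estimated correlation). Of 22 surface receptors and regulators 9 rose and 9 fell (18 adjusted over the list alone). Their median was 0.23 at 60 min, or -0.02 with library size alone (camera, Benjamini-Hochberg adjusted p = 9.16e-04; adjusted p = 0.0758 with an estimated correlation). C5ar1, a complement receptor, rose by 2.93 ± 0.16, Ptger4, a prostaglandin receptor, by 2.53 ± 0.21 and Fpr2, a formyl peptide receptor, by 2.2 ± 0.17, while the nucleotide receptor gene P2ry6 changed by -2.84 ± 0.24. On the authors' own levels C5ar1 stood at -0.037 by limma. With a straight line in time in place of the curve, changes were -1.19 for Nr4a1, -0.10 for Nfkbid, -3.23 for Zfp36 and -0.43 for Ptger4.

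Few antigen presentation and housekeeping genes passed the test in total RNA. Of 12 MHC class II genes 2 rose (2 adjusted over the list alone), Ciita, their transcriptional activator, by 1.16 ± 0.13 and H2-Ob by 1.04 ± 0.40. The call of H2-Ob was lost without the 15 min library (adjusted p = 0.0846) or the 180 min library (0.0590) or with library size alone (0.371) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The list's median was 0.37 at 60 min and 0.68 at 180 min (0.12 and 0.07 with library size alone; camera, Benjamini-Hochberg adjusted p = 6.76e-04 and 4.63e-04, and adjusted p = 0.241 and 0.251 with an estimated correlation). H2-Eb1 stood at 0.96 ± 0.11 and H2-Ab1 at 0.90 ± 0.12, both under the range threshold. On the authors' own levels H2-Eb1 stood at 0.19 and H2-Ab1 at -0.11. Of 47 ribosomal protein genes 1 rose (1 adjusted over the list alone), Rpl27 by 1.09 ± 0.31, a call that was lost without the 165 min library and with library size alone (edgeR, Benjamini-Hochberg adjusted p = 0.0555 and 0.556). Of 34 oxidative phosphorylation genes 1 was called (1 adjusted over the list alone), Ndufs3 at 0.62 ± 0.25, which stood at -0.91 without the 0 min library and at -0.57 without the 45 min library. The ribosomal median was -0.09 at 60 min and 0.40 at 180 min (camera, Benjamini-Hochberg adjusted p = 0.0453 and 2.16e-04), or -0.34 and -0.20 with library size alone. The oxidative phosphorylation median was -0.12 and 0.40 (camera, Benjamini-Hochberg adjusted p = 0.0276 and 2.51e-04), or -0.36 and -0.21 with library size alone. With an estimated correlation the adjusted p = 0.496 and 0.275 for ribosomal proteins and 0.468 and 0.251 for oxidative phosphorylation.

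In glucose metabolism 3 of 17 genes rose in total RNA (3 adjusted over the list alone), the hexokinases Hk2 by 2.05 ± 0.13 and Hk3 by 1.35 ± 0.10 and the phosphofructokinase Pfkp by 1.82 ± 0.11. The glycolysis median was 0.28 at 180 min, or -0.33 with library size alone (camera, Benjamini-Hochberg adjusted p = 0.00822; adjusted p = 0.334 with an estimated correlation). Of 28 cell cycle genes 8 fell and 1, Mki67 at 1.09 ± 0.13, rose (9 adjusted over the list alone). Cenpf, a centromere protein gene, changed by -1.90 ± 0.14, Aurka, a mitotic kinase, by -1.65 ± 0.15, and the cyclins Ccne1 and Ccne2 by -1.58 ± 0.17 and -1.45 ± 0.17. The cell cycle median was -0.21 at 60 min and -0.53 at 180 min, or -0.46 and -1.14 with library size alone (camera, Benjamini-Hochberg adjusted p = 0.00383 and 2.53e-04; adjusted p = 0.333 and 0.251 with an estimated correlation). In cholesterol synthesis, Insig1 (1.20 ± 0.17) rose and Dhcr7 (-0.73 ± 0.18) fell. Of 32 splicing factors Tra2a (1.20 ± 0.13) rose and Sf3a1 (-1.13 ± 0.17) fell (2 adjusted over the list alone). Of 9 noncoding RNA genes Snhg12 (-2.25 ± 0.51), Snhg5 (-1.58 ± 0.31) and Dleu2 (-0.57 ± 0.20) fell (3 adjusted over the list alone), though Snhg5 stood at -0.42 or -0.81 on the authors' own levels and was not called there. Neither splicing factors nor noncoding RNA genes were called as a list by camera in total RNA.

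Markers of cell types that a dendritic cell culture could hold passed the test in a few genes. Of 10 dendritic cell markers 1 fell (1 adjusted over the list alone), Clec9a by 1.24 on the log2 scale. By spliced junction reads alone this call was lost (edgeR, Benjamini-Hochberg adjusted p = 0.193), as was that of Spib below (0.0548). Another dendritic cell marker, Xcr1, passed as a rise with a spline of 3 degrees of freedom (2.39; edgeR, Benjamini-Hochberg adjusted p = 0.0467) and in 3 fits without 1 library. Of 9 macrophage markers 2 rose (2 adjusted over the list alone), the scavenger receptor Marco by 1.97 ± 0.16 and Mertk by 1.66 ± 0.16. The macrophage median was 0.29 at 60 min and 0.38 at 180 min, or 0.04 and -0.23 with library size alone (camera, Benjamini-Hochberg adjusted p = 0.0453 and 0.0463; adjusted p = 0.294 and 0.251 with an estimated correlation). Of 11 neutrophil markers 2 fell (2 adjusted over the list alone), Cxcr2 (-2.45 ± 0.35) and Csf3r (-0.77 ± 0.15), the latter at 0.47 and 0.59 by limma on the authors' own levels. Of 5 plasmacytoid dendritic cell markers Tcf4 (2.22 ± 0.16), Ccr9 (2.17 ± 0.54) and Bst2 (1.43 ± 0.13) rose and Spib (-1.61 ± 0.37) fell (4 adjusted over the list alone). Of 3 T cell markers Lck (3.56 ± 1.02) and Tcf7 (0.95 ± 0.39) rose (2 adjusted over the list alone). None of the 2 B cell, 4 mast cell and 7 stromal markers and of 1 replication histone gene was called (0 adjusted over the list alone), while natural killer and erythroid markers were under the count filter. The stromal gene Pdgfrb did pass with DESeq2 (Benjamini-Hochberg adjusted p = 0.0326), and by edgeR's Benjamini-Hochberg adjusted p with a spline of 3 degrees of freedom (0.0269), a straight line (0.00671) and in 4 fits without 1 library. Cdh5 passed with the line (edgeR, Benjamini-Hochberg adjusted p = 0.0371) and Col1a2 without the 30 min library (0.0454). Genes named here and in what follows because a count was 5 or fewer were chosen after their values were seen.

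In all, 3620 of 11048 tested genes changed in total RNA, 1505 up and 2115 down, at adjusted p under 0.05 and a fitted log2 range of at least 1, and 7811 passed the p alone (edgeR quasi-likelihood, Benjamini-Hochberg). Scaled by library size alone the split was 956 up and 3979 down, since that scaling moves the median of all genes from 0.00 to -0.25 at 60 min and from -0.02 to -0.63 at 180 min. On the authors' levels limma gave 950 up and 661 down with a pseudocount of 1 and 1141 and 1016 with 0.1. Directions here are thus relative to the bulk of genes and depend on the scaling.

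**Figure D2:**
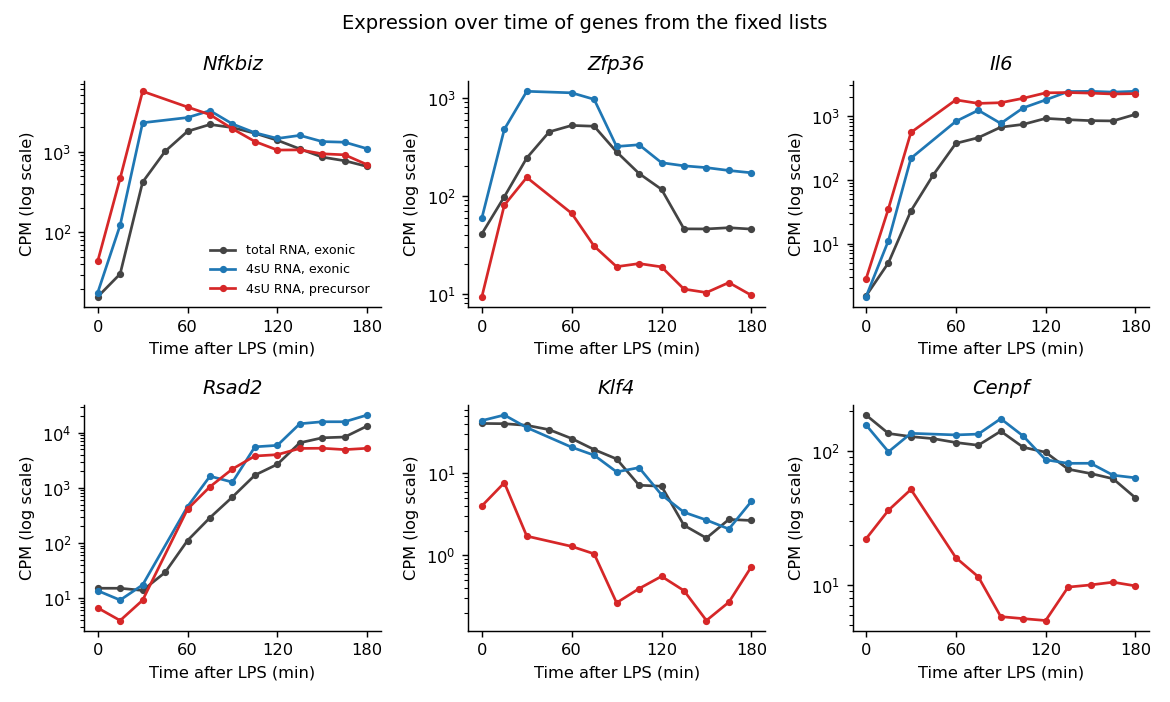
Observed CPM (log axis) of Nfkbiz, Zfp36, Il6, Rsad2, Klf4 and Cenpf against minutes after LPS, for exonic reads of total and 4sU RNA and precursor reads of 4sU RNA.

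Exonic reads of the 4sU libraries follow the RNA purified for 4sU at each time, although the 0 and 90 min libraries were close to total RNA in their spliced share. In them Nos2 rose by 11.49 ± 0.90 (from 0.233 to 416 CPM), Ifit1 by 11.26 ± 0.95 (from 4.39 to 6435 CPM), Rsad2 by 11.22 ± 0.90 (from 13.6 to 21120.5 CPM) and Il6 by 11.01 ± 0.56 (from 1.46 to 2427 CPM). Ereg peaked at 60 min with 11 ± 0.87 (from 0.200 to 162 CPM), while Oasl1 reached 10.85 ± 0.86 at 180 min. Il27, a cytokine subunit gene with 2 counts at 0 min, was higher by a ratio of 2369.8 (95% counting interval 654 to 19594). Iigp1, an interferon-induced GTPase gene of a family of similar copies, also with 2 counts, was higher by 4169.8 (1153 to 34456). Cxcl11 and Il12a had 0 counts at 0 min and were at least 322-fold and at least 402-fold higher at 180 min. Among the falls were Tiam2 (-4.64 ± 0.63), Synpo (-4.59 ± 0.53), Fam214a (-4.54 ± 0.39), Arhgap39 (-4.33 ± 0.53), and Cnr2 (-4.09 ± 0.37). Klf4 (-4.09 ± 0.34), Dna2 (-3.95 ± 0.43), Lpin1, a phosphatidate phosphatase gene (-3.96 ± 0.38), and the receptor gene Cd300lb (-3.81 ± 0.37) fell too. Zfp324 had its fitted low at 75 min (-4.05 ± 0.53, from 13.4 to 1.09 CPM), and stood at 2.62 with a straight line in time. Adjusted p of these 20 genes lay between 6.42e-10 and 2.25e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

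Immune lists again rose in 4sU RNA. All 26 cytokine genes rose (26 adjusted over the list alone; medians 5.74 at 60 min and 5.18 at 180 min, or 5.39 and 4.77 with the 3 genes at 0 counts at 0 min set to their bound). All 31 interferon response genes rose (31 adjusted over the list alone; medians 1.2 and 5.91, the same with the 2 genes at 0 counts set to their bound, or 0.76 and 5.12 with library size alone). Of 20 NF-kappaB feedback genes 19 rose (19 adjusted over the list alone; 1.75 and 2.12, or 1.27 and 1.34 with library size alone), with Tnfaip3 at 6.28 ± 0.63 and Nfkbiz at 8.23 ± 0.70. Of 20 maturation genes 16 rose (16 adjusted over the list alone; 1.68 and 2.68). Of 21 immediate early genes 17 rose and Klf4, Egr2 (-3.21 ± 0.49), Myc (-2.63 ± 0.47) and Klf2 (-1.23 ± 0.32) fell (21 adjusted over the list alone; 3.4 and 0.92, or 2.92 and 0.11 with library size alone). By camera with Benjamini-Hochberg adjustment the adjusted p at 60 and 180 min was 1.94e-34 and 1.69e-21 for cytokines, 1.63e-10 and 1.06e-30 for interferon response, 6.89e-20 and 3.53e-14 for NF-kappaB feedback and 2.41e-14 and 2.44e-11 for maturation, and 1.30e-19 at 60 min for immediate early genes. In the same order the adjusted p = 0.0531 and 0.120, 0.268 and 0.120, 0.0643 and 0.149, 0.0736 and 0.149, and 0.0643 with an estimated correlation. The reference of each of these changes is the 0 min library, whose junction reads were 91.5% spliced.

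Of 32 splicing factors 11 rose in 4sU RNA (11 adjusted over the list alone). Tra2a, a regulator of alternative splicing, rose by 1.99 ± 0.23 and Hnrnpc by 1.06 ± 0.25. The list's median was 0.52 at 60 min and 0.46 at 180 min, or 0.05 and -0.32 with library size alone (camera, Benjamini-Hochberg adjusted p = 5.02e-04 and 0.0116; adjusted p = 0.350 and 0.528 with an estimated correlation). Of 27 Toll-like receptor pathway genes 15 rose and Tlr4 (-0.71 ± 0.32), Irf3 (-1.66 ± 0.31) and Tirap (-1.09 ± 0.30) fell (18 adjusted over the list alone). The pathway had a median of 0.42 and 1.11, or -0.04 and 0.34 with library size alone (camera, Benjamini-Hochberg adjusted p = 5.02e-04 and 8.05e-05; adjusted p = 0.229 and 0.165 with an estimated correlation). Of 22 surface receptors 10 rose and 6 fell (16 adjusted over the list alone), with a median of 0.36 at 60 min, or -0.11 with library size alone (camera, Benjamini-Hochberg adjusted p = 1.99e-04; adjusted p = 0.0552 with an estimated correlation). Of 28 cell cycle genes 13 fell and Mki67 (1.82 ± 0.35), Pcna (1.44 ± 0.33), E2f1 (0.90 ± 0.31) and Bub1b (0.60 ± 0.19) rose (17 adjusted over the list alone). The cell cycle list had a median of -0.92 at 180 min, or -1.71 with library size alone (camera, Benjamini-Hochberg adjusted p = 3.77e-04; adjusted p = 0.480 with an estimated correlation). Of 34 mRNA decay genes 10 rose and Zfp36l1 (-2.84 ± 0.41), Pan2 (-1.61 ± 0.40), Edc3 (-1.28 ± 0.29) and Lsm1 (-1.25 ± 0.40) fell (14 adjusted over the list alone). All of these lists lean on a 0 min library with 45% intron reads, against 68.4% to 79.3% in 10 of the other libraries.

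The other lists in 4sU RNA hold housekeeping, metabolic and marker genes. Ciita (1.48 ± 0.31) alone rose of 12 MHC class II genes (1 adjusted over the list alone). Of 49 ribosomal protein genes Rps27 (3.15 ± 0.86), Rpl24 (2.26 ± 0.43), Rps24 (1.57 ± 0.37) and Rpl38 (0.96 ± 0.38) rose and Rpl8 (-1.10 ± 0.31) and Rps16 (-1.01 ± 0.36) fell (2 adjusted over the list alone). Ndufa2 (-0.85 ± 0.31) fell of 34 oxidative phosphorylation genes (0 adjusted over the list alone), with a median of -0.36 at 60 min, or -0.85 with library size alone (camera, Benjamini-Hochberg adjusted p = 0.0278; adjusted p = 0.770 with an estimated correlation). Hk2 (2.69 ± 0.32), Pfkp (1.39 ± 0.26) and Hk3 (0.89 ± 0.21) rose and Pdk1 (-1.29 ± 0.31) fell of 17 glycolysis genes (4 adjusted over the list alone). Of cholesterol genes Insig1 (1.66 ± 0.25) and Idi1 (1.55 ± 0.25) rose and Dhcr7 (-1.75 ± 0.36), Mvd (-1.13 ± 0.23) and Lss (-1.02 ± 0.30) fell. Snhg8 (1.96 ± 0.41), Snhg5 (1.02 ± 0.58) and Dleu2 (0.70 ± 0.37) rose and Gas5 (-1.22 ± 0.40) fell of 9 noncoding RNA genes (5 adjusted over the list alone). The departures of Snhg5 and Dleu2 lay within 2 SE of 0, and both genes fell in total RNA. Among markers, Xcr1 (4.96 ± 0.72), Zbtb46 (1.4 ± 0.36) and Kit (0.63 ± 0.36) rose and Dpp4 (-1.77 ± 0.49) and Batf3 (-0.87 ± 0.42) fell of 10 dendritic cell genes (6 adjusted over the list alone). The departure of Kit lay within 2 SE of 0. Marco (2.05 ± 0.28) and Mertk (2.06 ± 0.29) rose and Csf1r (-1.13 ± 0.28) fell of 9 macrophage genes (3 adjusted over the list alone). Of 11 neutrophil genes Cxcr2 (-2.76 ± 0.38), S100a8 (-1.35 ± 0.49), Csf3r (-1.13 ± 0.24), Ltf (-1.10 ± 0.29) and Retnlg (-1.03 ± 0.41) fell (5 adjusted over the list alone). The neutrophil list had a median of -0.79 at 180 min, or -1.60 with library size alone (camera, Benjamini-Hochberg adjusted p = 0.0432; adjusted p = 0.528 with an estimated correlation). Tcf4 (3.22 ± 0.27), Ccr9 (3.24 ± 0.73) and Bst2 (1.57 ± 0.26) rose and Spib (-1.44 ± 0.48) fell of 5 plasmacytoid genes (5 adjusted over the list alone). The histone gene H2bc4 (-0.83 ± 0.33) fell. None of 2 B cell, 1 T cell, 4 mast cell and 5 stromal markers was called (0 adjusted over the list alone). Changes in these lists too are set against the 0 min 4sU library, which was close to total RNA in its spliced share.

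Of 11040 tested genes, 4534 changed in 4sU RNA, 2379 up and 2155 down (edgeR quasi-likelihood, Benjamini-Hochberg), and without the 0 and 90 min libraries 5038, of which 3888 were the same genes, 344 of them with the opposite direction. Scaled by library size alone the split was 1379 up and 5542 down, as that scaling moves the median of all genes from -0.10 to -0.57 at 60 min and from -0.16 to -0.94 at 180 min.

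Precursor RNA, read from introns and their boundaries in the 4sU libraries, moved in most genes. Nos2 precursors rose by 11.66 ± 0.90 (from 0.569 to 714 CPM), those of Ifit1 by 11.22 ± 1.05, of Rsad2 by 10.41 ± 0.86 (from 6.64 to 5254 CPM) and of Htra4 by 11.26 ± 0.69. Isg15, a ubiquitin-like interferon-induced gene, rose by 11.08 ± 0.56 to its fitted peak at 75 min (from 0.108 to 70.8 CPM), and Plagl1, a zinc finger gene, by 11.27 ± 0.95 at 90 min (from 0.135 to 34.6 CPM). Ereg precursors had 0 counts at 0 min and were at least 1376-fold higher at 60 min, with a fitted change that stood at -4.79 with a straight line in time. Ifi214, of a family of similar copies, had 2 counts at 0 min and a ratio of 981 (95% counting interval 271 to 8106). Among the largest falls were those of Chn2, a Rac-regulating gene, at -6.87 ± 0.30 (from 655 to 7.0 CPM), and Synpo at -6.64 ± 0.55. They were followed by the potassium channel gene Kcnq1 at -6.19 ± 0.64 and the sialyltransferase gene St6gal1 at -6.08 ± 0.48 (from 121 to 1.88 CPM). Chn2 total RNA stood at 0.19 ± 0.09 over the same time. Adjusted p of these 12 genes lay between 4.42e-09 (Chn2) and 4.05e-06 (Ifit1) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

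In precursors all 27 cytokine genes rose (27 adjusted over the list alone; medians 5.76 at 60 min and 4.22 at 180 min, or 5.02 and 3.97 with the 2 genes at 0 counts at 0 min set to their bound). All 31 interferon response precursors rose (31 adjusted over the list alone; 2.66 and 6.10, the same with the gene at 0 counts set to its bound, or 1.5 and 5.22 with library size alone). Of 20 NF-kappaB feedback genes 19 rose (19 adjusted over the list alone; 3.23 and 2.12, or 2.02 and 1.22 with library size alone), among them Nfkbiz by 7.28 ± 0.78 and Tnfaip3 by 6.23 ± 0.58. Of 20 maturation genes 17 rose and Pdcd1lg2 (-1.31 ± 0.34) fell (18 adjusted over the list alone; 3.12 and 2.88, or 1.91 and 1.95 with library size alone). Immediate early precursors split into 13 up and 8 down of 21 (21 adjusted over the list alone; 2.51 and -1.10, or 1.18 and -1.97 with library size alone). By camera with Benjamini-Hochberg adjustment, a test of lists on precursors chosen after seeing the data, the adjusted p at 60 and 180 min was 9.47e-12 and 5.27e-10 for cytokines, 3.90e-07 and 5.93e-20 for interferon response, 7.41e-09 and 1.12e-06 for NF-kappaB feedback and 2.12e-06 and 5.86e-06 for maturation, and 5.60e-05 at 60 min for immediate early genes. In the same order the adjusted p = 0.329 and 0.114, 0.329 and 0.0698, 0.344 and 0.362, 0.344 and 0.362, and 0.379 with an estimated correlation. These lists too are set against the 0 min library with its 45% intron reads.

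Of 32 splicing factor precursors 17 rose and Srsf9 (-1.33 ± 0.30), Hnrnpl (-1.25 ± 0.17) and Srsf2 (-1.02 ± 0.29) fell (20 adjusted over the list alone). Splicing factor precursors had a median of 0.96 at 60 min, or -0.27 with library size alone (camera, Benjamini-Hochberg adjusted p = 0.00149; adjusted p = 0.379 with an estimated correlation). Of 27 Toll-like receptor pathway genes 16 rose and 6 fell (22 adjusted over the list alone). Their medians were 0.90 and 0.83, or -0.37 and -0.06 with library size alone (camera, Benjamini-Hochberg adjusted p = 0.0104 and 0.0150; adjusted p = 0.344 and 0.362 with an estimated correlation). Of 49 ribosomal protein genes 16 rose, with Rpl24 at 3.56 ± 0.30, and Rpl10a (-1.89 ± 0.30), Rpsa (-1.36 ± 0.28), Rps16 (-0.86 ± 0.34) and Rpl28 (-0.62 ± 0.34) fell (20 adjusted over the list alone). Ribosomal protein precursors had a median of 0.54 at 60 min, or -0.71 with library size alone (camera, Benjamini-Hochberg adjusted p = 0.00181; adjusted p = 0.770 with an estimated correlation). Of 28 cell cycle genes 8 rose and 19 fell (27 adjusted over the list alone), with a median of -0.95 at 180 min, or -1.88 with library size alone (camera, Benjamini-Hochberg adjusted p = 0.0351; adjusted p = 0.827 with an estimated correlation). Of 21 surface receptors 10 rose and 9 fell (19 adjusted over the list alone), with a median of 0.51 at 60 min, or -0.80 with library size alone (camera, Benjamini-Hochberg adjusted p = 0.0212; adjusted p = 0.621 with an estimated correlation). Counts rising and falling were 13 and 10 for 34 mRNA decay genes, 7 and 3 for 12 MHC class II genes, and 3 and 11 for 34 oxidative phosphorylation genes. They were 7 and 6 for 17 glycolysis genes and 3 and 1 for 9 noncoding RNA genes. Among markers they were 3 and 6 for 9 dendritic cell, 2 and 6 for 9 macrophage, 2 and 5 for 10 neutrophil, 3 and 0 for 5 plasmacytoid, 3 and 0 for 4 stromal and 1 and 1 for 3 T cell genes, with Marco (4.90 ± 0.22) and Bst2 (4.43 ± 0.24) among the rises.

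Precursors of 8505 of 11190 tested genes changed, 3734 up and 4771 down (edgeR quasi-likelihood, Benjamini-Hochberg), and without the 0 and 90 min libraries 8159, of which 7674 were the same genes, 590 of them with the opposite direction. Scaled by library size alone the split was 1605 up and 7647 down, as that scaling moves the median of all genes from -0.21 to -1.45 at 60 min and from -0.13 to -1.03 at 180 min. A straight line in time in place of the curve called 3982 genes.

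The order of precursor, exonic 4sU and total RNA was read from the 1306 genes that rose in all 3. The fitted curve passed 50% of its rise within 180 min at a median of 31 min in precursors, 53 min in exonic 4sU RNA and 75 min in total RNA. Total RNA passed that mid-rise point after the precursor in 97.0% of genes, by a median of 36 min. The fitted maximum lay at the last sampled time, 180 min, in 883 genes in total RNA and 253 in precursors, so that no lag by the maximum is given. In total RNA immediate early genes were earliest, with mid-rise medians of 18, 20 and 28 min in precursors, exonic 4sU and total RNA (13 genes). NF-kappaB feedback had 18.5, 24 and 38.5 min (18 genes), cytokines 20, 23.5 and 43 min (26 genes) and surface receptors 18, 23 and 46 min (9 genes). Interferon response genes were late in each, at 68, 95 and 107 min (31 genes), and maturation genes lay between at 25.5, 35 and 52 min (16 genes). In Nfkbiz the 3 mid-rise times were 18, 19 and 24 min, in Il6 20, 24 and 30 min, in Cd40 33, 56 and 62 min and in Rsad2 57, 65 and 82 min. These times describe fitted curves across genes, which are not independent replicates, and no test was made.

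**Figure D3:**
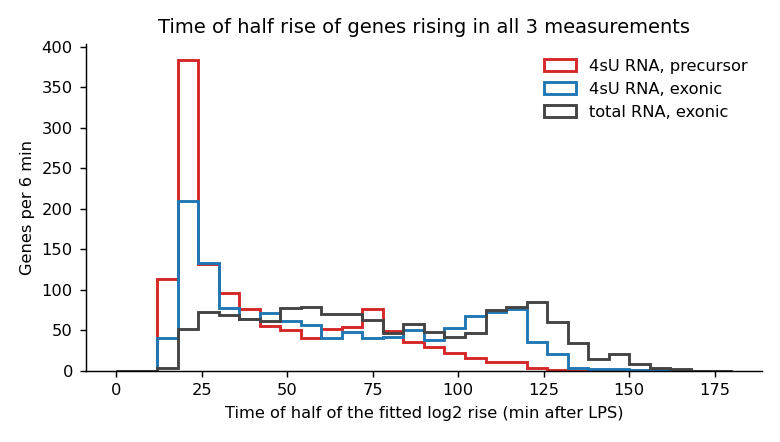
Genes per 6 min by the time at which the fitted log2 curve passed 50% of its rise, for precursors, exonic 4sU RNA and total RNA of the 1306 genes that rose in all 3.

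Calls in the 3 readouts overlapped in direction. Of 10923 genes tested in all, 1341 rose in both total and exonic 4sU RNA and 1296 fell in both, where independent lists would share 327.8 and 417.3. For total RNA and precursors 1401 rose and 1714 fell in both (514.5 and 923.8 for independent lists). Opposite calls were fewer, 71 genes up in total RNA with falling precursors and 97 the reverse (657.4 and 723.0). Both fractions come from the same RNA samples, so part of the overlap may come from shared samples.

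Some genes followed another course in 4sU than in total RNA, which the interaction of fraction and time tests. Values are log2 of the 4sU over total change between 0 and 180 min. Their reference is the 0 min pair, whose 4sU library was close to total RNA in makeup. A gene with a steady 4sU to total ratio at the other times could therefore also show a difference here. Among genes that rose further in 4sU RNA, Mterf1a, a mitochondrial transcription termination factor gene, gave 3.76 ± 0.61 (4sU from 5.19 to 29.3 CPM), Rbm12b2 2.86 ± 0.36 (4sU from 19.4 to 161 CPM) and the interferon-induced Ifi44 2.85 ± 0.53 (4sU from 0.466 to 160.0 CPM). Ifit1bl2, of a family of similar copies, gave 2.99 ± 0.56, but 0.59 without the 0 min pair, and 9330175E14Rik 2.85 ± 0.65, or 2.71 without that pair. Both calls were then lost (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.190 and 0.265). Il27 gave 2.94 ± 0.82, but 1.39 with a spline of 3 degrees of freedom (edgeR, Benjamini-Hochberg adjusted p = 0.535). Among genes that fell further or rose less in 4sU RNA, Ereg gave -3.73 ± 1.17, Tmem241 -2.84 ± 0.64, Pold1, a DNA polymerase subunit gene, -2.12 ± 0.36 (4sU from 41.0 to 3.42 CPM) and Ypel3 -2.09 ± 0.49. Pfkm, a phosphofructokinase gene, gave -2.58 ± 0.53 and the methyltransferase gene Prmt7 -2.20 ± 0.52. Both calls were lost without the 180 min pair, at -1.88 and -0.88 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0705 and 0.0638), that of Prmt7 also without the 15 min pair (0.0516). With no time point block, edgeR's Benjamini-Hochberg adjusted p passed the threshold for neither Il27 (0.314), Pfkm (0.0745), Prmt7 (0.0745) nor Ifit1bl2 (0.0538). By spliced junction reads alone Ereg stood at -4.89, Tmem241 at -5.50, Pold1 at -1.91 and Ypel3 at -1.86. Their calls were lost there (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.138, 0.132, 0.0695 and 0.299), as were those of Il27, Pfkm and Prmt7. With all pairs and the block, edgeR's Benjamini-Hochberg adjusted p was between 5.33e-05 (Ereg) and 0.0190 (Prmt7).

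By list, courses differed in 20 of 31 interferon response genes, all toward 4sU RNA (23 adjusted over the list alone; median difference at 180 min 0.79), Rsad2 at 1.51 ± 0.50 among them. They differed in 11 mRNA decay genes toward 4sU RNA and 1 away of 34 (13 adjusted over the list alone), and 8 and 4 of 20 immediate early genes (13 adjusted over the list alone). Toward and away stood 10 and 7 of 26 cytokines (20 adjusted over the list alone) and 7 and 2 of 20 NF-kappaB feedback genes (10 adjusted over the list alone), with Tnfaip3 at 1.34 ± 0.38. Away from 4sU RNA stood 10 of 34 oxidative phosphorylation genes with none toward it (12 adjusted over the list alone; median -0.52), 3 of 17 glycolysis genes (7 adjusted over the list alone) and 2 of 12 MHC class II genes (2 adjusted over the list alone). Of 46 ribosomal protein genes 8 stood away and 2 toward (12 adjusted over the list alone). These differences are read against a 0 min 4sU library close to total RNA in makeup, at 91.5% spliced junction reads against 92.7% in its total RNA partner.

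Courses differed in 2309 of 10661 genes (edgeR quasi-likelihood, Benjamini-Hochberg), 1656 toward 4sU RNA and 653 away, or 1276 and 1338 with library size alone. Without the 0 and 90 min pairs 2936 were called (1815 the same, 145 of them with the opposite direction), but without the 30 min pair 1391 and without the 165 min pair 1442. Calls numbered, with a spline of 3 degrees of freedom 1385, with no time point block 1284, with a difference of at least 1 at 180 min 975, and with spliced junction reads alone 27, of which 26 were the same genes.

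Averaged over the 12 pairs, the ratio of 4sU to total RNA sets a transcript's share of the exonic reads of 4sU RNA against its share in total RNA. Rgs1, a regulator of G protein signalling (NM_015811, mm9 chromosome 1, 146091914 to 146096169), stood at 2.83 ± 0.25 (log2 of 4sU over total ± SE), and was higher in 4sU RNA in 11 of 12 pairs. Its mean levels were 223 CPM in total RNA and 1924 CPM in 4sU RNA. Mterf1a stood at 2.71 ± 0.32 (12 of 12 pairs), Iigp1 at 2.78 ± 0.22 (9 of 12; adjusted p = 0.0550 with no time point block by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Fndc7 at 2.51 ± 0.17 (12 of 12). The autophagy gene Vmp1 stood at 2.3 ± 0.21, with 239 CPM in total RNA and 1307 CPM in 4sU RNA (12 of 12 pairs). Gm7609 stood at 2.5 ± 0.22 (12 of 12), Mplkip at 2.20 ± 0.22 (11 of 12) and 9330175E14Rik at 2.18 ± 0.26 (11 of 12). Under-represented were Ipo11, a nuclear import receptor gene (-1.40 ± 0.19, higher in 1 of 12 pairs), and Plxnb2 (-1.12 ± 0.12, 1 of 12). So were Nlrp1c-ps (-1.15 ± 0.13), Hacd4 (-1.14 ± 0.15), Mospd2 (-1.13 ± 0.13), Fancd2, of DNA repair (-1.11 ± 0.16), Zranb3 (-1.08 ± 0.15) and Lrp1, an endocytic receptor gene (-1.08 ± 0.11, 1537 CPM in total RNA and 761 CPM in 4sU RNA), each of these 6 higher in 0 of 12 pairs. Adjusted p of these 16 genes lay between 3.18e-08 (Fndc7) and 1.20e-05 (Fancd2) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

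Immediate early genes had a median of 0.97 in 4sU over total RNA, at percentile 100 of 10000 random lists of equal size and expression, and 10 of 20 were over-represented (10 adjusted over the list alone). Cytokines had 0.89 (percentile 100; 11 of 26; 11 adjusted over the list alone), interferon response genes 0.79 (percentile 100; 10 of 31; 10 adjusted over the list alone) and noncoding RNA genes 0.58 (99.1). Splicing factors had 0.38 (99.9), NF-kappaB feedback 0.38 (99.3), maturation 0.36 (98.8), surface receptors 0.29 (97.8), mRNA decay 0.20 (96.8), ribosomal proteins 0.18 (96.9) and the Toll-like receptor pathway 0.18 (93.1). Below 0 lay dendritic cell markers at -0.57 (percentile 0.050), MHC class II at -0.33 (1.20), macrophage markers at -0.31 (2.35), and oxidative phosphorylation at -0.26 (0.140). Nearer to 0 were glycolysis at -0.23 (2.88) and cell cycle at -0.14 (8.64), with neutrophil markers at -0.02 (43.9). Zfp36 (1.56 ± 0.18), Tnfaip3 (1.38 ± 0.16), Il6 (1.34 ± 0.16) and Snhg5 (1.91 ± 0.24) were each higher in 4sU RNA in 12 of 12 pairs. The 0 and 90 min pairs enter these means with 4sU libraries of 91.5% and 87.4% spliced junction reads.

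Of 10661 genes 590 passed a 2-fold threshold (edgeR quasi-likelihood, Benjamini-Hochberg), 527 over- and 63 under-represented, or 395 and 109 with library size alone, and 6166 differed at any fold. Without the 0 and 90 min pairs 882 passed (581 the same genes), and with spliced junction reads alone 168 (69 the same genes).

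The authors' model gave production, processing and degradation of 7872 genes over the same course, as half-lives. The median processing half-life was 12 min (quartiles 7.40 and 17.6), and 337 genes, or 4.28% (95% Wilson interval 3.86 to 4.75), had a value that changed over time. The median degradation half-life was 144.7 min (76.7 and 269.3), with 791 genes, 10% (9.40 to 10.7), changing and 666 held at the highest value of 693.1 min. The Wilson intervals treat genes as independent and do not cover error of the model or its libraries. Production changed in 98.2%. Immediate early transcripts had a median degradation half-life of 39.3 min and splicing factors of 74.1 min, both at percentile 0 of 10000 random lists, surface receptors of 55.8 min and noncoding RNA genes of 11.3 min (both at 0.010). The lowest list median, 1 min, was that of 6 neutrophil markers (percentile 0). H2-Ab1, Lrp1, St6gal1 and Rpl24 stood at 0.7 min throughout. Whether values this short are limits of the model was not tested. Ribosomal protein transcripts had 106.4 min (percentile 2.25), or 48.4 min by the values at 0 min (0.060). Interferon response genes had 693.1 min (percentile 100), MHC class II 306.6 min (96.5), NF-kappaB feedback 290.6 min (98.6) and maturation genes 285.3 min (98.6), or 617.6 min by the values at 0 min. Between 0 and 180 min the half-life went from 57.4 to 12.5 min for Zfp36, from 301.4 to 20.5 min for Tnfaip3, from 693.1 to 31.2 min for Nfkbiz and from 139.9 to 26.6 min for Socs3. It lengthened from 24.8 to 693.1 min for Fcgr1 and from 7.1 to 194.9 min for Insig1. For Lss it went from 12.8 to 165.5 min and for Rps16 from 2.2 to 81 min, and other named genes changed either way. The half-life was constant at 32.1 min for Il6, 32.9 min for Klf4 and 693.1 min for Rsad2 and Cd40. The model used the 0 min 4sU library, which was close to total RNA in makeup. Whether that shaped the values at 0 min, and so these changes, was not tested.

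Genes that rose in total RNA had a median degradation half-life of 226.1 min, and 16.9% of the 1164 had one that changed, against 73.0 min and 9.09% of the 1078 that fell and 159.6 min and 8.82% of the 5625 not called. Across genes, which are not independent replicates, the log2 change of the production value (lower is faster) and the fitted precursor change had a Spearman correlation of -0.67 at 180 min and -0.56 at 60 min (7864 genes). Degradation half-life and the 4sU to total ratio had -0.40 (7854 genes), and these 3 were the relations computed. The model was fitted by the authors to these same libraries, and its 4sU levels at 45 min equal the mean of 30 and 60 min in 7872 of 7872 genes (relative tolerance 0.0001), against 14 in total RNA.

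In the zebrafish library, 10232 loci had a mature and a precursor level on a log scale whose base, taken as 2 from its floor, is inferred. Mature levels had a median of 3.05 and lay at the floor of -8 in 215 loci (2.1%), and precursor levels lay there in 6234 (60.9%). In the 3945 loci with both above the floor, mature exceeded precursor by a median of 9.03, with a Spearman correlation across loci of -0.17. The loci carry no gene names, so maternal and zygotic genes were not analysed here, and the depth is unknown.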

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

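Of the tests here, the change in cells at 90 min and the exchange with total RNA libraries were chosen after the result was seen, as were all fits without the 0 and 90 min libraries and those on junction reads alone.

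The interaction of fraction and time was past its threshold in 2309 genes, the difference between the courses of 4sU and total RNA. Reads on stretches that are exon in some transcripts and intron in others, which no comparison uses, reached 2.58% of a total RNA library and 2.16% of a 4sU library.

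The 4sU libraries at 0 and 90 min held 91.5% and 87.4% spliced reads among junction reads, against 55.1% to 72.5% in the other 10. An exchange with the total RNA library of the same time would need that partner to look like labelled RNA, and the lower of the 2 partners had 92.7% spliced junction reads, which argues against it. Carry-over of unlabelled RNA would flatten the gene-by-gene 4sU to total ratios, and their slope on the mean ratio of the other pairs was 0.0557 at 0 min and 0.367 at 90 min, both below the lowest slope of any other pair (0.464), so unlabelled RNA in these libraries is a candidate explanation. A change of the cells at 90 min cannot be told apart from it by the total RNA library, whose intron to exonic ratio deviated by -0.21 (log2) from its neighbours, a fall exceeded at another time (-0.27), against -1.66 in the 4sU library. For 0 min no biological explanation was tested, since the design has 1 unstimulated sample.

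Genes over-represented in 4sU RNA (527 past the threshold) may owe it to unspliced reads inside exons, to length or to short-lived transcripts. Enough junction reads were held by 216 of the 527, against 8846 of the 10661 genes tested, and the cause was not tested. Of these 216, 27.8% (60 genes) were also at least 2-fold over-represented in spliced junction reads, between the bounds set for and against unspliced reads. The median ratio of the 216 was 1.18 by exonic and 0.73 by junction reads. The median exon length of all 527 was 1.17 times that of the other genes (1536 against 1309 bases), again between the bounds. For short life the immediate early list lay at percentile 100 as predicted, while the ribosomal protein list, predicted to lie low, lay at 96.9. Most immediate early genes also rose after LPS, so their high ratio does not isolate short life. A rise in production was not weighed as an explanation here. The 3 explanations cannot be told apart on these values, nor by the authors' half-lives, which were fitted to the same libraries and are 106.4 min for ribosomal proteins but 693.1 min for interferon response and 290.6 min for NF-kappaB feedback genes, whose ratios lay at percentiles 100 and 99.3.

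Time labels were shuffled, or fraction labels swapped within pairs, in 100 draws for each count of genes, the real order included. Only 1 of 100 draws, the real one, gave as many genes in each comparison, so random orders of these libraries seldom give such counts. This does not cover drift or a batch along the single series. The shuffled orders were the same for 4sU RNA, precursors and the difference of courses, so these are not separate checks. In total RNA 3620 genes changed against 2321 at most in another draw, 4534 against 1903 in 4sU RNA, 8505 against 1266 in precursors, 2309 against 1586 for the difference of courses and 590 against 413 for over- or under-representation in 4sU RNA. No gene was called in 94, 97, 94, 86 and 95 draws, in the same order, and why a few draws called many genes was not tested.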

How the results depend on the processing

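List tests on precursors and alternatives on library size alone, junction or intron reads alone, a difference of at least 1 at 180 min and all fits without the 0 and 90 min 4sU libraries were chosen after seeing the data. Size factors, count filters, DESeq2 and the 5 degree spline kept every count of called genes within 1.5 times, and the lag of total behind precursor RNA by the mid-rise time was 30 min on raw values, 34 min with the 5 degree spline and 39 min without the 0 and 90 min 4sU libraries.

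Total RNA changes numbered 7811 with no range threshold, as its removal must raise it, and 1611 and 2157 by limma on the authors' levels with pseudocounts of 1 and 0.1, which hold fewer genes (7872). The same 2 fits gave 1386 and 2124 for 4sU RNA and 2331 and 5050 for precursors. For 4sU RNA library size alone gave 6921 and junction reads 2638, for precursors a straight line gave 3982, and the cause was not tested. The difference of courses was called in 1385 genes with 3 degrees of freedom, 975 with a difference of at least 1 and 27 by junction reads. Over-representation was called in 6166 genes with no fold threshold and 168 by junction reads. Junction reads left 8846 of 10661 genes to test in both of these comparisons, and in total RNA they called 2965 genes, and the cause of the lower counts was not tested. With an estimated correlation 3 of 40 list calls remained. By fry 50 were called, 38 of them among the 40, and without the 0 and 90 min 4sU libraries 43, with all 40 among them. Leaving out these libraries does not touch the calls in total RNA, and it extends the 4sU curve back to 0 min with no library there. Processing half-lives changed in 7.07% of junctions, whose median half-lives were 16.9 min for processing and 110.7 min for degradation, the cause not tested. With no replicate block for time point, the pairing of fractions, the difference of courses was called in 1284 genes, and the block changed no other count of calls by over 1.5 times (547 against 590 for over-representation), though Il27, Pfkm, Prmt7, Ifit1bl2 and Iigp1 lost their calls.

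Leaving out each time point gave 3288 to 3907 genes for total RNA, 3991 to 5064 for 4sU RNA, 8194 to 8480 for precursors, 1391 to 2834 for the difference of courses and 514 to 725 for over-representation.

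Among results of named genes past the adjusted p threshold in the main fit, 31 alternatives reversed a sign. Ndufs3 stood between -0.91 and 0.70 over fits without 1 library (-0.91 and -0.57 without 0 or 45 min), -0.52 with 3 degrees of freedom, -0.70 with library size alone and -0.76 by junction reads. With a straight line Nr4a1 stood at -1.19, Nfkbid at -0.10, Zfp36 at -3.23, Slc2a1 at -0.037, Ptger4 at -0.43, Fcgr1 at 0.00166, Zfp324 in 4sU RNA at 2.62 and Ereg precursors at -4.79, since a line cannot follow a course that turns. By limma on the authors' levels with pseudocounts of 1 and 0.1, Zfp36l1 stood at 2.13 and 2.33, H2-Ab1 at -0.11 and -0.11, Cyc1 at -0.33 and -0.34, C5ar1 at -0.037 and -0.037, Itgax at -0.57 and -0.57, Adgre1 at -0.10 and -0.11 and Csf3r at 0.47 and 0.59, and the cause was not tested. With library size alone Ndufb3 stood at -0.21, Cyc1 at -0.38, Slc2a1 at -0.61 and Adgre1 at -0.14, where the scaling moves the median of all genes by as much. Over all 159 results of named genes, 3647 of 3786 values were counted as unchanged. That count includes any sign change of a result not past the threshold in the main fit. With the sign kept, 81 values lost the threshold (37 results) and 27 gained it (7 results), and the 31 reversals are counted apart from these.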

Other observations

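Of the tests in this part, the comparison with falling genes and both tests on falling genes were chosen after the result was seen, and the fits of 4sU RNA without the 0 and 90 min libraries were chosen after seeing the data.

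Introns along long genes changed in order of their distance from the gene start. In total RNA, 279 rising genes with at least 5 introns and a span of at least 60 kb gave a median within-gene rank correlation of 0.76 between distance and mid-rise time, positive in 88.5%, with a median slope of 4.17 kb per min (95% bootstrap interval over genes 3.86 to 4.52). In 216 falling genes the correlation was 0.90, positive in 97.7%, with 2.87 kb per min (2.74 to 3.08). Both intervals resample genes that share the same single libraries, so they do not cover error between libraries or cultures. In 4sU RNA the slopes were 4.59 kb per min in 440 rising and 3.16 in 438 falling genes, and 4.17 and 3.5 without the 0 and 90 min libraries. In Dock2, a signalling gene spanning 469.6 kb whose introns fell, reads of the intron 13.7 kb from the gene start passed the midpoint of their fall at 24.5 min in total RNA and those of the intron at 465.0 kb at 170.7 min (36 introns, rank correlation 0.91, 3.53 kb per min).

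The order among introns of rising and falling genes was weighed as 1 pattern. Shallow counts of distal introns are argued against, since the median correlation was 0.900 in 135 rising and 0.905 in 25 falling genes with introns of at least 200 mean counts. The correlation of 0.900 in falling genes shows that the order is not limited to rising genes. Being from other genes, it cannot exclude an order set by read counts within the rising genes. A polymerase that leaves a gene from its start after production stops may give the falling order, as the fall time of the last intron rose with gene span across genes (rank correlation 0.723, against 0.351 for the first intron). For rising genes the same across-gene correlation was 0.0818 (SE 0.0602), against 0.0558 for the first intron. It lay under the bound set beforehand as speaking against passage of the polymerase after a synchronous start, but by less than its SE. Allowing for the SE, which the preset bound did not, that passage cannot be told apart from other orders there. In total RNA with introns of at least 200 mean counts the correlation was 0.208, against 0.186 for the first intron. In the sets of rising genes from 4sU RNA, with and without the 0 and 90 min libraries, it was 0.131 to 0.227. These values lay between the bounds set for and against passage. Genes also rose at different times.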
